A study of Mus musculus with 54 samples.

How the data were processed

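Messenger RNA was measured on oligonucleotide arrays in neural retina of C3H mice that were wild type (WT) or homozygous for the rd1 allele. Per the labels, retinas were dissected at 12 postnatal ages (PN, in days), total RNA was purified on a caesium gradient, and biotin-labelled cRNA was made by in vitro transcription. The labels call the arrays biological replicates and do not say how many animals each array holds. There were 54 arrays, 27 per genotype. PN7, PN8, PN9, PN11 and PN13 had 3 arrays per genotype, PN5, PN6, PN12, PN15 and PN21 had 2, and PN28 and PN35 had 1. No batch or collection date is given in the labels.

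The deposited table holds 1 intensity per probe set and array, on a linear scale, for 45037 probe sets. RMA was the summary method per the submitters' processing notes, which give no version and do not say whether all arrays were normalized together. The values ran from 9.37 to 21708 and their medians per array from 127 to 134, so their distributions had been made nearly equal between arrays. A log2 scale had been assumed when the design was written, so log2 was taken here. Background and detection calls were not used here, and no minimum intensity was applied. The number of arrays limits the precision of every value.

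Each probe set was assigned to the gene symbol that the array annotation gives. Of the probe sets, 34945 named 1 symbol, 932 named several and 9160 named none, and those naming several or none were left out. For the 9010 genes with more than 1 probe set, the probe set with the highest mean log2 value over all arrays stood for the gene, which left 18193 genes. Chromosome positions came from the GRCm38.p6 gene table for 18145 genes. A call and its value therefore refer to 1 probe set, and other probe sets of the same gene can differ.

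Differences were fitted with limma 3.58.1 in R 4.3.3 on the 50 arrays of the 10 ages with at least 2 arrays per genotype. The model had 1 mean per genotype and age, 30 residual degrees of freedom, and moderated variances with an intensity trend. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over all genes within a contrast, with a threshold of 0.05. The contrasts were rd1 minus WT at each age, the unweighted mean of these differences in an early window (PN5, PN6, PN7 and PN8, 10 arrays per genotype), a middle window (PN9, PN11, PN12 and PN13, 11 arrays per genotype) and a late window (PN15 and PN21, 4 arrays per genotype). Further contrasts were the change of the difference from early to middle and from middle to late, and in WT the mean of PN15 and PN21 minus that of PN5 and PN6. Values are log2 differences, with the standard error (SE) of the fit after the sign ±. Between genotypes, a rise or fall is that of rd1 relative to WT of the same age, not a change with age. PN28 and PN35 have 1 array per genotype and were given as values without a test.

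Windows, contrasts, gene lists and the rule for named genes were set before the data were examined. The 30 lists, written from textbook knowledge, held 561 entries, of which 506 were measured. They covered rod, shared photoreceptor, cone, bipolar, amacrine, ganglion, horizontal, Müller glia, reactive glia, microglia and macrophage, complement and chemokine, interferon and antigen presentation, proteasome core, proteasome regulator, immunoproteasome, ubiquitin and protein quality control, endoplasmic reticulum stress, heat shock, cell death, oxidative stress, immediate early, glycolysis, oxidative phosphorylation, lysosome and autophagy, outer-segment phospholipid and retinoid, vascular, retinal pigment epithelium, lens, red blood cell, and progenitor and cell cycle genes. The interferon and immunoproteasome lists share Psmb8 and Psmb9. Pde6b is in no list. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry.

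The rule named, per window, the 5 largest rises and 5 largest falls past the threshold with the same sign at every age of the window. It also named up to 4 members per list with the largest absolute difference (members past the threshold first), the 3 largest changes each way per age and per test of change, the 5 largest each way in WT maturation, and always Pde6b. RIKEN clones, predicted genes and expressed sequence tags were passed over. The text gives a selection of these genes, and a gene named outside the rule is said to be chosen after its values were seen.

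Alternatives were quantile normalization, centring each array on the amacrine and ganglion cell genes, leaving out the dimmest 30% of genes, the mean of all probe sets of a gene, moderation without a trend, array weights, a fit of the compared arrays alone, a block for the replicate number, leaving out each array in turn, an estimated inter-gene correlation, and fry. Left-out ages and arrays that held muscle or lens transcripts were chosen after seeing the data.

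The procedure was tested on simulated data with known shifts in 67, 67 and 66 of 18193 genes. A shift of 1 log2 unit was recovered for 97.0% to 100% of genes in the contrasts simulated. A shift of 0.5 was recovered for 100% of genes in the early window, 98.5% in the middle window, 88.1% in the late window and 68.7% at PN12. Between 4 and 19 genes per contrast were called without a shift. A list of 20 genes shifted by 0.2 was called by camera with 0 other lists called, and the estimated correlation also gave 0 others. The genes were simulated independently of each other, whereas the estimated correlation in the measured data was 0.57 for rod and 0.92 for lens genes. The simulation therefore does not show how often camera calls lists of correlated genes without a shift. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.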

Results

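Retinal gene expression was compared between WT mice and rd1 mice, whose mutation in Pde6b, the beta subunit of the rod phosphodiesterase of the light response, leads to loss of rods in the weeks after birth. The 54 arrays covered 12 ages from PN5 to PN35, with 27 arrays per genotype, and each gave an intensity for 45037 probe sets, read as 18193 genes. Median intensity per array lay between 127 and 134. Pearson's r over genes within the 40 replicate pairs lay between 0.991 and 0.998; genes are not independent replicates. The SD of the log2 difference within a pair was 0.14 to 0.27. The series title names a cascade leading to a failing proteasome, and proteasome genes were therefore read beside the lists for cell types, stress and immunity. Only transcripts were measured, so their levels do not show whether proteasome protein or activity changed.

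Pde6b was lower in every rd1 array than in every WT array of its age at 12 of 12 ages (27 against 27 arrays). The difference was -1.52 ± 0.09 in the early window (adjusted p = 8.01e-15), -1.56 ± 0.09 in the middle window (9.51e-17) and -4.73 ± 0.15 in the late window (2.46e-26). At single ages it was -1.49 ± 0.21 at PN5, -1.79 at PN13, -3.15 at PN15 and -6.31 ± 0.21 at PN21, a fold of 79.2. At PN6 it was -0.81 and was not called over all genes (adjusted p = 0.556, 2 arrays per genotype). In a fit of the compared arrays alone Pde6b was called at PN6 but not at PN5. The rd1 arrays of PN5 read 9.53 and 10.95, and without rd1 PN5 replicate 1 the difference at PN5 was -0.78 (adjusted p = 0.0185).

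**Figure D1:**
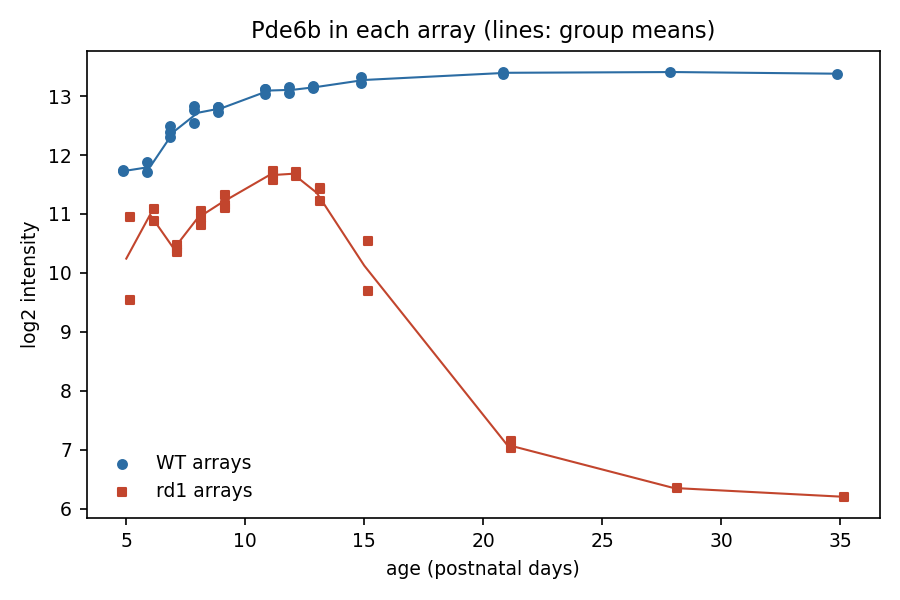
Log2 intensity of Pde6b in each array against postnatal age, with WT and rd1 as separate points and lines through the group means. Every rd1 point lies below every WT point of its age, with a difference of means of -1.49 at PN5, -0.81 at PN6, -1.42 at PN12, -6.31 at PN21, -7.05 at PN28 and -7.17 at PN35.

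The retinas of the 2 genotypes were nearly alike in the first week and differed in 3920 genes at PN15 and 6442 at PN21. Immediate early genes were called in 2 of 17 at PN9 and 9 of 17 at PN11, and microglia genes in 4 of 24 at PN11 and 19 of 24 at PN13. Reactive glia genes were called in 3 of 23 at PN11 and 12 of 23 at PN13. Rod genes were called lower in 1 of 17 at PN11, 14 of 17 at PN13 and 17 of 17 at PN15. Genes shared by rods and cones were called lower in 1 of 23 at PN11 and 17 of 23 at PN13. The order of these changes was not tested. The counts of genes higher and lower in rd1 were 9 and 3 at PN5, 2 and 1 at PN6, 1 and 2 at PN7, 2 and 3 at PN8, 5 and 2 at PN9, 79 and 28 at PN11, 112 and 42 at PN12, 744 and 620 at PN13, 2249 and 1671 at PN15, and 4325 and 2117 at PN21. Fos, an immediate early transcription factor, was the clearest example, at 1.18 at PN9 (adjusted p = 1.98e-05) and 3.38 ± 0.16 at PN11 (5.68e-19). It was at 3.14 at PN12, 2.66 at PN13, 1.58 at PN15 and -0.33 at PN21 (not called, 0.195). Egr1, of the same class, rose by 2.71 at PN11 and Nr4a1, an orphan nuclear receptor of that class, by 2.33 at PN12. S100a6, a calcium-binding protein, rose by 2.69 at PN13, 2.99 at PN15 and 2.85 at PN21. B2m, the light chain of class I antigen presentation, and C1qa, a complement subunit made by microglia, rose by 2.79 and 2.78 at PN15. Pdzph1 fell by 1.29 at PN11, 1.97 at PN13 and 5.67 at PN21, Fscn2, an actin-bundling protein of photoreceptors, fell by 2.30 at PN15, and Cnga1, the rod cyclic nucleotide-gated channel, fell by 5.25 at PN21. Ttr, the thyroid hormone carrier made by pigment epithelium, rose by 2.82 ± 0.40 at PN21 and Slc26a7, an anion exchanger, by 2.67. Usp18, an interferon-induced protease, fell by 1.91 ± 0.46 at PN13 (adjusted p = 0.004), and without WT PN13 replicate 2 it was -1.55 (0.0576).

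Several of these counts rested on single arrays. The 12 calls at PN5 became 6 without WT PN5 replicate 1 and 23 without rd1 PN5 replicate 1. The 3 calls at PN6 became 6 without WT PN6 replicate 2 or rd1 PN6 replicate 2 and 1 without rd1 PN6 replicate 1, and the 3 at PN7 became 9 without WT PN7 replicate 1. The 5 calls at PN8 became 49 without WT PN8 replicate 3, and 3 without WT PN8 replicate 1, WT PN8 replicate 2 or rd1 PN8 replicate 2. The 107 calls at PN11 became 57 without rd1 PN11 replicate 1, and the 154 at PN12 became 70 without WT PN12 replicate 1, 66 without rd1 PN12 replicate 1 and 62 without rd1 PN12 replicate 2. The 3920 calls at PN15 became 2294 without rd1 PN15 replicate 1. Centring on amacrine and ganglion cell genes changed the split of higher and lower calls to 7 and 5 at PN5, 2 and 0 at PN6, 2 and 2 at PN7, 2 and 4 at PN8, 50 and 42 at PN11, 52 and 73 at PN12, 397 and 946 at PN13, 313 and 11334 at PN15, and 856 and 12695 at PN21. Quantile normalization changed it to 2 and 2 at PN7, 1 and 4 at PN8, 84 and 43 at PN11, and 123 and 77 at PN12.

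**Figure D2:**
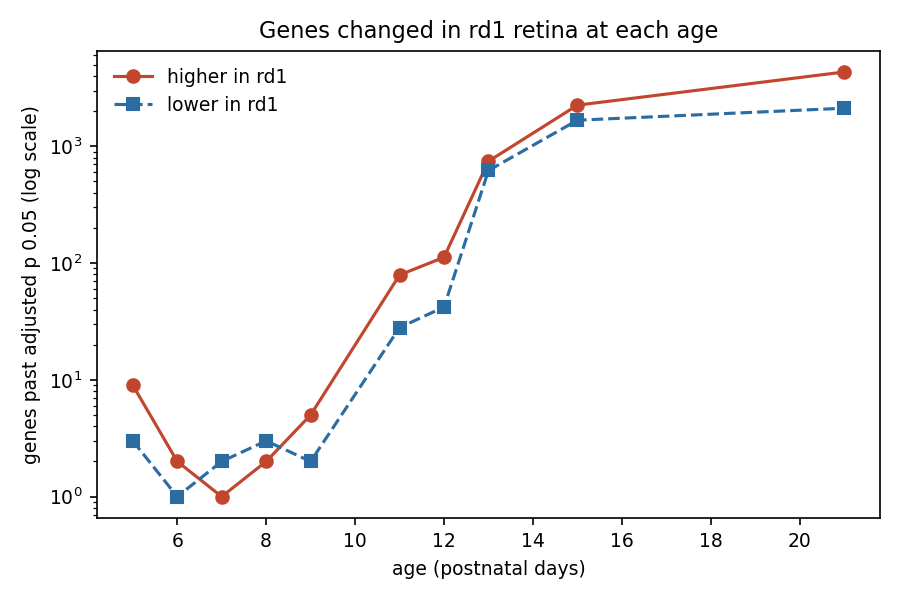
Number of genes past adjusted p of 0.05 (log axis) against postnatal age, for genes higher and lower in rd1. The total rises from 12 at PN5 to 1364 at PN13 and 6442 at PN21; at PN12, PN13, PN15 and PN21 the higher side becomes the smaller one (52, 397, 313 and 856) when arrays are centred on amacrine and ganglion cell genes.

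In the early window the rd1 retina differed from WT in 15 genes, 10 higher and 5 lower, and none of the 30 lists held a called gene. The largest rise was Dipk1a, a kinase-like protein, at 1.47 ± 0.06 (adjusted p = 1.71e-21, 10 arrays per genotype). It was higher at PN6 (1.27), PN7 (1.60), PN8 (1.73) and PN9 (1.67) alike. After Pde6b, the largest falls were Zfp33b, a zinc finger protein, at -0.93 ± 0.07 (3.23e-13), Tmod2, a cap of actin filaments, at -0.47 (0.0116) and Lrrc8c, a subunit of the volume-regulated anion channel, at -0.28 (1.02e-04). Tlcd3a was at -0.24 (0.0447). Mtf2, a Polycomb partner, at 0.24 (1.02e-04) and Rpap2, an RNA polymerase II phosphatase, at 0.25 (0.0049) were higher. Muscle genes formed a second group. Acta1, skeletal muscle actin, rose by 0.63 ± 0.08 (1.94e-05), and Tnnt3, a troponin of fast muscle, by 0.29 (0.0492). Tnnc2 (0.51, 0.0047), Myl1 (0.42, 0.0285) and Myh8 (0.40, 0.0285), which encode further contractile proteins of skeletal muscle, and Cplx1, a synaptic complexin (0.21, 0.0049), were higher too and were chosen after their values were seen. At PN5 alone Acta1 rose by 1.85 ± 0.18 (2.04e-08) and Tnnc2 by 1.75 ± 0.20 (8.43e-07). The largest rise at that age was Col3a1, a collagen, at 2.04 ± 0.34 (0.0012).

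Of the called genes, 7 lay within 20 Mb of Pde6b on its chromosome, namely Pde6b, Dipk1a, Zfp33b, Lrrc8c, Mtf2, Cplx1 and Rpap2. Dipk1a stayed higher in the middle (1.17) and late (0.95) windows, and Zfp33b stayed lower in the middle window (-0.87). Lrrc8c and Tmod2, lower in the early window, were called higher in the late window, Lrrc8c at 0.27 (adjusted p = 5.65e-04; -0.13, 0.0558 when centred on amacrine and ganglion cell genes) and Tmod2 at 0.36 (0.0415; -0.044, 0.773 when centred). The late call of Tmod2 ended without WT PN15 replicate 1, rd1 PN15 replicate 1, WT PN21 replicate 1 or rd1 PN21 replicate 1 (0.148 to 0.265), under quantile normalization (0.0698) and with the mean of all probe sets (0.551). Without PN5, whose rd1 arrays held the muscle transcripts, 8 genes were called and 7 of them were shared with the full window, while Acta1 was at 0.23 (adjusted p = 0.9997). The count was 9 without rd1 PN6 replicate 1. Single left-out arrays ended the calls of Tnnt3 and Tlcd3a in 15 cases each (adjusted p up to 0.476 and 0.380), of Myl1 in 12 (up to 0.362) and of Myh8 in 10 (up to 0.348). The call of Tmod2 ended without WT PN5 replicate 1, rd1 PN5 replicate 1 or rd1 PN6 replicate 1 (0.0583 to 0.108). That of Tnnc2 ended without rd1 PN5 replicate 1 (0.0503) or rd1 PN6 replicate 1 (0.0777), that of Rpap2 without rd1 PN5 replicate 1 (0.0503), and that of Cplx1 without WT PN6 replicate 1 (0.0607). As the mean of all probe sets Rpap2 was lower (-0.19, 0.0481) and Mtf2 was at 0.013 (0.999). In a fit of the early arrays alone the calls of Tnnt3 (0.293), Tlcd3a (0.171), Tnnc2 (0.124), Myl1 (0.274), Myh8 (0.212), Cplx1 (0.124) and Rpap2 (0.0810) ended.

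Camera called 5 lists in the early window, each with 0 genes called by limma. Shared photoreceptor genes (median 0.05, 23 genes, adjusted p = 0.0108) and oxidative phosphorylation genes (0.03, 30 genes, 0.0177) lay higher, and Müller glia (-0.02, 19 genes, 0.0092), pigment epithelium (-0.09, 13 genes, 0.002) and lens genes (-0.42, 16 genes, 5.37e-04) lay lower. With an estimated correlation none of these 5 calls held (adjusted p = 0.946 for each, with an estimated correlation), and fry called 0 lists. At an unadjusted p under 0.05 there were 1 shared photoreceptor, 2 Müller, 2 pigment epithelium, 0 oxidative phosphorylation and 0 lens genes. Lens genes averaged 12.56 on the log2 scale in WT PN7 replicate 3 against 6.22 and 6.38 in the other WT arrays of that age, and without it the lens median was 0.12 (0.368). The number of lists became 2 without rd1 PN6 replicate 1 or WT PN8 replicate 3, 3 without rd1 PN5 replicate 2 or WT PN7 replicate 3, 8 without WT PN7 replicate 2 and 9 without WT PN8 replicate 2. The shared photoreceptor call also ended without WT PN6 replicate 1, the Müller call without WT PN6 replicate 2 or rd1 PN7 replicate 2. The pigment epithelium call ended without WT PN8 replicate 3, and the oxidative phosphorylation call without rd1 PN5 replicate 1, WT PN6 replicate 1, rd1 PN7 replicate 1, rd1 PN7 replicate 3, WT PN8 replicate 1 or rd1 PN8 replicate 2.

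In the middle window, around the onset of rod loss, immediate early genes and the chaperones Hspa1a and Hspa1b showed the largest rises. Reactive glial and microglial genes rose as well, and rod genes had begun to fall below WT. Within rd1 the rod list mean per array still went up, from 10.99 to 11.12 at PN9 to 11.50 to 11.53 at PN13. In WT it was 10.96 to 11.08 and 12.02 to 12.08. Whether slower maturation of rods gives this gap was not tested. Fos rose by 2.59 ± 0.08 (6.02-fold, adjusted p = 4.82e-25, 11 arrays per genotype), and Egr1 by 2.01 ± 0.10 (1.19e-18). Fosb, a partner of Jun proteins like Fos, rose by 1.80 ± 0.06 (8.90e-24), Nr4a1 by 1.70 ± 0.05 (4.82e-25) and Hspa1b, an inducible Hsp70 chaperone, by 1.54 ± 0.08 (1.19e-18). The largest falls after Pde6b were Cltrn, a collectrin that chaperones amino acid transporters, at -0.90 ± 0.08 (7.81e-11), Zfp33b at -0.87 ± 0.06, Lrp4, a receptor for agrin, at -0.75 ± 0.05 (7.78e-16), and Glb1l2, a galactosidase-like protein, at -0.72 ± 0.06 (9.84e-12). In all, 1030 genes were called, 595 higher and 435 lower, and 12 rises and 2 falls reached 2-fold. Under centring on amacrine and ganglion cell genes the split was 285 higher and 826 lower, and under quantile normalization 565 and 579. Without PN13, the age with most calls in the window, 229 genes were called, 161 higher and 68 lower, and 223 of them were shared with the full window.

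Of 17 immediate early genes 10 rose and 1 fell, the same as adjusted over the list alone (median 0.27, camera adjusted p = 7.26e-26). Junb, a Fos partner, rose by 0.80 and Dusp1, a phosphatase that ends MAP kinase signals, by 0.68, while Ier3 fell by 0.19. Of 13 heat shock genes 4 rose, and 5 adjusted over the list alone (median 0.06, mean 0.28, 1.56e-08), with Hspa1a at 1.26 and its nucleotide exchange factor Hsph1 at 0.28. Of 20 endoplasmic reticulum stress genes 6 rose, also 6 adjusted over the list alone (median 0.08, 3.03e-07). They held Chac1 (0.51), Trib3 (0.44) and Ddit3 (0.27), targets of the integrated stress response, and Eif2ak3 (0.48), the kinase PERK. Of 16 oxidative stress genes 4 rose, and 6 adjusted over the list alone (median 0.11, 6.45e-05), among them the metallothioneins Mt1 (0.69) and Mt2 (0.39) and Srxn1, which restores peroxiredoxins (0.23). Of 18 lysosome and autophagy genes 7 rose, and 10 adjusted over the list alone (median 0.10, 6.85e-07), with the proteases Ctsz at 0.44, Ctsd at 0.29 and Ctsh at 0.27.

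**Figure D3:**
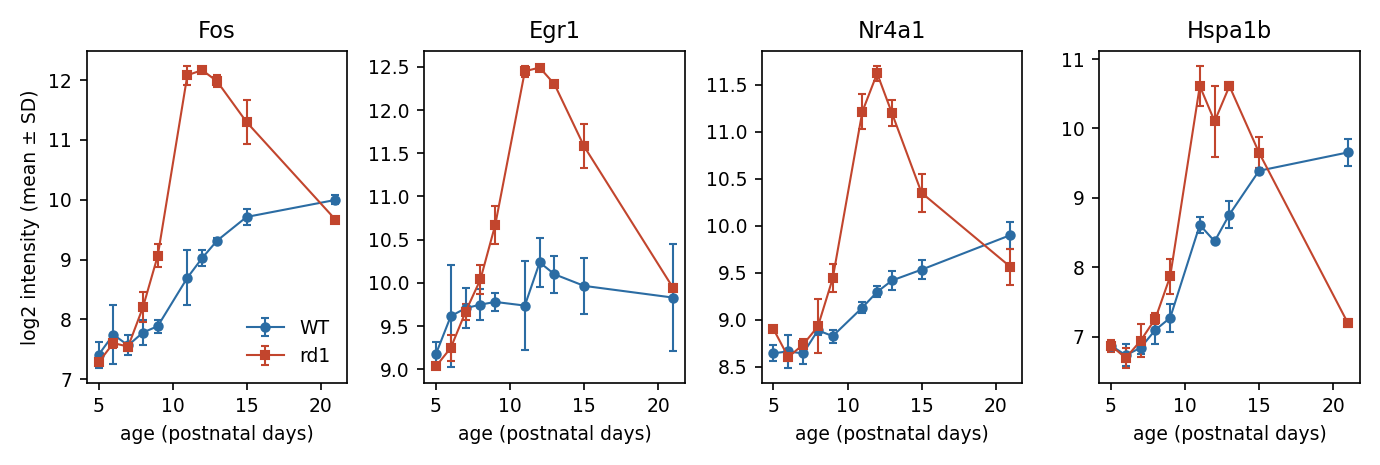
Log2 intensity of Fos, Egr1, Nr4a1 and Hspa1b against postnatal age, as mean and SD of the arrays of each genotype. Fos is higher in rd1 from PN9 (1.18) to PN15 (1.58) with its highest difference at PN11 (3.38), and the rd1 mean of Hspa1b lies below WT at PN21 (-2.46).

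Reactive glia genes rose in 11 of 23, also 11 adjusted over the list alone (median 0.13, mean 0.28, camera adjusted p = 1.38e-15), led by S100a6 (1.14 ± 0.12), Cebpd, an acute-phase transcription factor (1.09), Edn2, an endothelin released by stressed photoreceptors (0.80), and Gfap, the glial intermediate filament (0.78). Microglia and macrophage genes rose in 17 of 24, and 18 adjusted over the list alone (median 0.27, 3.56e-27). Cd68, a lysosomal marker of phagocytes, was at 0.78 and the complement subunits C1qc and C1qa and the surface protein Ly86 at 0.57 each. By age the microglia median was 0.17 at PN11, 0.31 at PN12 and 0.69 at PN13, and the reactive glia median 0.10, 0.14 and 0.57. Of 19 Müller glia genes 3 rose, and 8 adjusted over the list alone (median 0.08, 6.12e-04; adjusted p = 0.214 with an estimated correlation), with the glutamate transporter Slc1a3 at 0.21 and Gpr37 at 0.16.

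Of 17 rod genes 10 fell, and 14 adjusted over the list alone (median -0.17, camera adjusted p = 4.08e-15, or 0.0389 with an estimated correlation), among them Guca1b, an activator of guanylate cyclase (-0.62), Susd3 (-0.49), and the channel subunits Cnga1 (-0.35) and Cngb1 (-0.32). Of 23 genes shared by rods and cones 9 fell, and 15 adjusted over the list alone (median -0.16, 4.08e-15, or 0.0389 with an estimated correlation), with Fscn2 at -0.69, the retinol dehydrogenase Rdh12 at -0.34, Guca1a at -0.32 and the retinoid transporter Abca4 at -0.29. Cone genes went the other way, with 2 of 15 higher and 6 adjusted over the list alone (median 0.07, 0.0151; adjusted p = 0.233 with an estimated correlation), and the cone arrestin Arr3 rose by 0.27. Of 19 bipolar genes 1 rose, also 1 adjusted over the list alone (median 0.10, 0.0066; adjusted p = 0.294 with an estimated correlation). Of 18 amacrine genes 1 rose, also 1 adjusted over the list alone (median 0.06, 0.0368; adjusted p = 0.312 with an estimated correlation). The amacrine call ended (0.0504 to 0.0848) without WT PN9 replicate 2, rd1 PN9 replicate 2, WT PN11 replicate 3, WT PN12 replicate 1 or rd1 PN12 replicate 2. The 16 ganglion cell genes had a median of 0.05 (0.0368; adjusted p = 0.456 with an estimated correlation) with 0 called by limma, 1 at an unadjusted p under 0.05 and a fry adjusted p of 0.118. That call ended (0.0562 to 0.0981) without rd1 PN9 replicate 2, WT PN11 replicate 3, rd1 PN11 replicate 1, WT PN12 replicate 1, rd1 PN12 replicate 2 or WT PN13 replicate 2. The 7 horizontal cell genes were not called (median 0.09, 0.195), with 0 genes called, 3 at an unadjusted p under 0.05 and a fry adjusted p of 0.0232.

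Proteasome genes were close to WT in this window. The 14 genes of the 20S core and the 21 of the 19S regulator each had a median of 0.02 (-0.03 each when centred on amacrine and ganglion cell genes), with camera adjusted p of 0.324 and 0.395. Limma called 0 genes of either list, fry gave adjusted p of 0.514 and 0.617, and 0 core and 1 regulator gene had an unadjusted p under 0.05. The 7 immunoproteasome and 11S activator genes had a median of 0.07 (0.0877), with 0 called, 3 at an unadjusted p under 0.05 and a fry adjusted p of 0.0375. The 15 ubiquitin and protein quality control genes were called by camera (median 0.06, 0.0027; adjusted p = 0.290 with an estimated correlation) with 0 genes called by limma, 5 at an unadjusted p under 0.05 and a fry adjusted p of 0.0296. Of 24 cell death genes 2 rose, and 5 adjusted over the list alone. Camera did not call the list (median 0.04, -0.0035 when centred, adjusted p = 0.0521), while fry gave an adjusted p of 0.0027.

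Of 12 outer-segment phospholipid and retinoid genes 2 fell, and adjusted over the list alone 3 fell and 1 rose (median -0.03, camera adjusted p = 0.0388; adjusted p = 0.135 with an estimated correlation), with the retinal reductase Dhrs3 at -0.23. That call ended (0.0518 to 0.102) without WT PN9 replicate 1, rd1 PN9 replicate 3, WT PN11 replicate 3, rd1 PN11 replicate 1, WT PN12 replicate 2, rd1 PN12 replicate 1, WT PN13 replicate 1 or rd1 PN13 replicate 1. Of 13 pigment epithelium genes 2 fell, also 2 adjusted over the list alone (median -0.06, 0.0098; adjusted p = 0.290 with an estimated correlation), the photoisomerase-like Rgr by 0.45 and the isomerase Rpe65 by 0.43, and without PN13 the median was 0.014 (0.987). At PN13 alone their median was -0.52 with 6 of 13 lower. Camera did not call vascular genes (1 higher and 1 lower of 15, adjusted p 0.139) or complement and chemokine genes (1 higher of 17, median 0.02, -0.02 when centred, 0.518). Neither were glycolysis genes (1 lower of 16, median 0.05, -5.36e-05 when centred, 0.174) called. Lists with 0 genes called by limma were interferon and antigen presentation (median -0.04, 0.395), progenitor and cell cycle (0.05, -0.0016 when centred, 0.139), lens (-0.22, 0.173), red blood cell (-0.01, 0.0019 under quantile normalization, 0.700) and oxidative phosphorylation genes (median below and mean above 0, test downward, 0.700). Of these, 1 interferon, 3 progenitor, 0 lens, 0 red blood cell and 0 oxidative phosphorylation genes had an unadjusted p under 0.05. Camera called 17 lists in all, and 9 held with an estimated correlation, namely rod and shared photoreceptor genes downward and reactive glia, microglia, endoplasmic reticulum stress, heat shock, oxidative stress, immediate early and lysosome genes upward. Their adjusted p was then 0.0389 for rod, shared photoreceptor, endoplasmic reticulum stress and oxidative stress genes and 0.0393 for lysosome genes. It was 0.0029 for heat shock, 1.19e-04 for reactive glia, 1.68e-06 for microglia and 1.57e-08 for immediate early genes. Without PN13 camera called 11 lists, and the cone (adjusted p 0.103), amacrine (0.0516), ganglion cell (0.0564), Müller glia (0.0564) and outer-segment calls (0.728) ended as well as that of pigment epithelium. With dim genes left out the cone (0.0638), bipolar (0.0773), amacrine (0.165) and ganglion cell calls (0.0773) ended, and under quantile normalization the amacrine (0.0778) and ganglion cell calls (0.0530). The outer-segment call ended with the mean of all probe sets (0.102) and with array weights (0.0873), and under centring the amacrine and pigment epithelium calls ended (0.0634 each).

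In the late window rod genes were far below WT, with a list median of -1.59 at PN15 and -4.15 at PN21. Genes of Müller glia, reactive glia and microglia were higher than in WT, with list medians above 0 under each scaling. The Müller median was 0.63 against 0.46 for bipolar, amacrine and ganglion cell genes together, and whether a lower share of rod RNA gives it was not tested. S100a6 rose by 2.92 ± 0.19 (7.57-fold, adjusted p = 3.30e-16, 4 arrays per genotype), and Mt2 by 2.49 ± 0.14 (5.70e-18). B2m rose by 2.49 ± 0.17 (1.22e-15), Serping1, the inhibitor of the first complement component, by 2.43 ± 0.11 (1.61e-21) and A2m, a protease inhibitor of the acute phase, by 2.29 ± 0.09 (1.30e-23). The largest falls after Pde6b were Pdzph1 at -4.50 ± 0.16 (2.00e-24), Cnga1 at -3.69 ± 0.08 (1.13e-30), the potassium channel Kcnj14 at -3.35 ± 0.19 (8.20e-18) and the nucleotidase Nt5e at -3.31 ± 0.07 (4.66e-31). Of 6823 called genes 4489 were higher and 2334 lower, with 84 rises and 311 falls of at least 2-fold. Centring on amacrine and ganglion cell genes moved the median late difference of all genes from 0.02 to -0.38 and the split to 736 higher and 14466 lower, so late rises are given relative to the array as a whole. Of the genes named for this window, the rises of Gnb3 (0.067, adjusted p = 0.344), Ccl9 (0.26, 0.0843), C1ra (0.25, 0.0815), Uchl1 (0.074, 0.155), Herpud1 (0.082, 0.207), Fos (0.23, 0.0986), Fosb (0.16, 0.203) and Flt1 (0.079, 0.324) were no longer called when centred. Quantile normalization gave 4130 higher and 2987 lower. Without PN21 there were 3947 calls, of which 3674 were shared.

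All 17 rod genes fell, also adjusted over the list alone (median -2.97, camera adjusted p = 6.49e-39), with Guca1b at -3.22, Susd3 at -3.18 and the phosphodiesterase subunit Pde6a at -3.17. All 23 shared photoreceptor genes fell, also adjusted over the list alone (median -1.83, 5.35e-44), among them the disc rim protein Prph2 (-3.19), Fscn2 (-3.13), Rdh12 (-3.11) and the matrix proteoglycan Impg1 (-2.83). The rod median was -0.51 at PN13, -1.59 at PN15 and -4.15 at PN21. Of 15 cone genes 8 rose and 2 fell, and 9 and 2 adjusted over the list alone, but the list was not called (median 0.33, -0.08 when centred with 2 higher and 7 lower; 0.0597). Arr3 rose by 1.03, the cone phosphodiesterase Pde6c by 0.93 and the cone transducin subunit Gnb3 by 0.47, and the thyroid hormone receptor Thrb fell by 0.58.

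Genes of inner retinal neurons were higher relative to the array as a whole. Of 18 amacrine genes 17 rose, also 17 adjusted over the list alone (median 0.44, near 0 by construction when centred, camera adjusted p = 2.46e-07), with the glutamate receptor Gria3 at 0.67 and the GABA genes Gad2 at 0.63 and Slc32a1 at 0.61; Slc32a1 was at 0.10 (0.408) as the mean of its probe sets. Of 19 bipolar genes 16 rose and 1 fell, and 17 and 1 adjusted over the list alone (median 0.52, 0.12 when centred with 7 higher and 2 lower, 5.72e-05; adjusted p = 0.138 with an estimated correlation), with the kainate receptor Grik1 at 0.81, the calcium channel Cacna1s at 0.75 and the neurokinin receptor Tacr3 at 0.75. Of 16 ganglion cell genes 14 rose, also 14 adjusted over the list alone (median 0.40, near 0 by construction when centred, 5.47e-05; adjusted p = 0.138 with an estimated correlation), with Ebf1 at 0.67 and the synuclein Sncg at 0.57. Of 7 horizontal cell genes 4 rose, also 4 adjusted over the list alone, and the list was not called (median 0.22, -0.18 when centred with 0 higher and 4 lower; 0.168).

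Of 19 Müller glia genes 17 rose, and adjusted over the list alone 17 rose and 1 fell (median 0.63, 0.23 when centred with 10 higher and 3 lower, camera adjusted p = 2.70e-09), with the lipid carrier Apoe at 1.19, the chaperone Clu at 1.02 and the carbonic anhydrase Car14 at 0.91. Of 23 reactive glia genes 15 rose, and 16 adjusted over the list alone (median 0.70, 0.30 when centred with 13 higher and 6 lower, 8.64e-10), with Cebpd at 2.08 and Gfap at 1.98. Of 24 microglia and macrophage genes 21 rose and 1 fell, also adjusted over the list alone (median 1.05, 0.65 when centred with 20 higher and 3 lower, 8.84e-18). C1qa rose by 2.28, C1qc by 2.18, Ly86 by 1.76 and the lysosomal protease Ctss by 1.70, while the protease Lgmn fell by 0.40. The microglia median was 1.33 at PN15 and 0.80 at PN21. Interferon and antigen presentation genes rose in 13 of 18, and 14 adjusted over the list alone (median 0.52, 0.12 when centred with 5 higher and 2 lower, 4.83e-04; adjusted p = 0.384 with an estimated correlation), with the antiviral Ifitm3 at 1.85. Their median was -0.23 at PN13, 0.69 at PN15 and 0.35 at PN21 (-0.085 when centred). Of 17 complement and chemokine genes 8 rose, also 8 adjusted over the list alone, with the chemokine Ccl9 at 0.66 and the protease C1ra at 0.65, and the list was not called (median 0.18, -0.22 when centred with 1 higher and 9 lower; 0.0898).

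**Figure D4:**
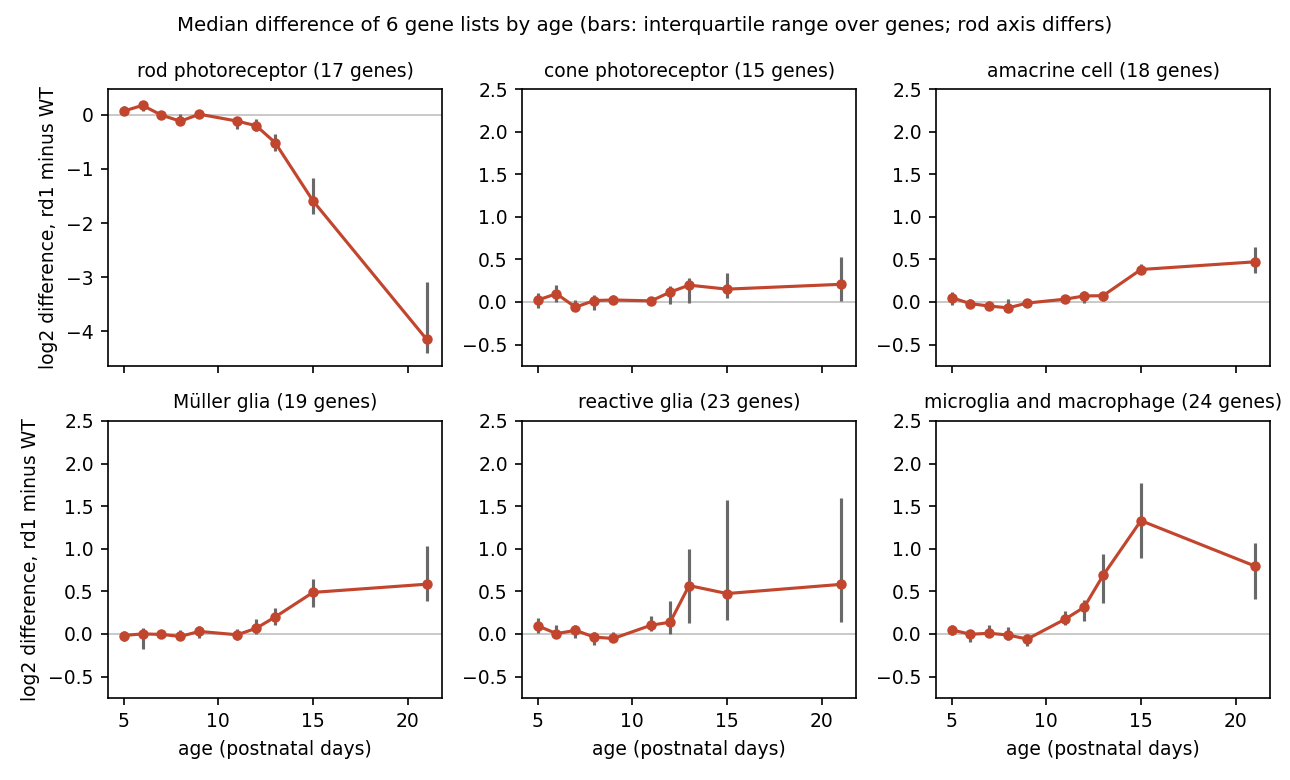
Median rd1 minus WT log2 difference of the genes of 6 lists against postnatal age, with bars for the interquartile range over genes and a wider axis for rod genes. Rod genes fall to -4.15 at PN21, microglia genes peak at 1.33 at PN15, and centring arrays on amacrine and ganglion cell genes turns the cone medians of PN15 and PN21 (0.15 and 0.21 to -0.21 and -0.23) and, at medians no farther from 0 than 0.067, those of cone genes at PN5 and PN11, Müller genes at PN6, PN7 and PN12, microglia genes at PN5 and PN8, reactive glia genes at PN6 and rod genes at PN7, while it holds the amacrine medians near 0 by construction.

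Genes of the inducible proteasome rose relative to the array as a whole. Of 7 immunoproteasome and 11S activator genes 5 rose, also 5 adjusted over the list alone (median 0.68, camera adjusted p = 0.0216; adjusted p = 0.139 with an estimated correlation), among them the activator subunit Psme1 (0.79) and the catalytic subunits Psmb9 (0.71), Psmb8 (0.70) and Psmb10 (0.68). When centred the median was 0.28, with 4 higher and 3 lower, and with dim genes left out the call ended (median 0.44, 0.130). Of 14 genes of the 20S core 6 rose, also 6 adjusted over the list alone, and the list was not called (median 0.12, -0.28 when centred with 0 higher and 14 lower; 0.192, fry 0.0354); Psma4 was at 0.21 and, when centred, at -0.19 (0.0032). Of 21 genes of the 19S regulator 6 rose and 3 fell, also adjusted over the list alone, and the list was not called (median 0.12, -0.28 when centred with 0 higher and 20 lower; 0.375); Psmd14 was at 0.29 and, when centred, at -0.11 (0.174). At PN15 limma called 0 core genes higher or lower, and 0 regulator genes higher and 1 lower. At PN21 it called 9 core genes higher and 0 lower (median 0.23, -0.21 when centred), and 11 regulator genes higher and 1 lower (median 0.20, -0.24 when centred). Centring moved the median of all genes to -0.34 at PN15 and -0.41 at PN21, so the counts at both ages hold for the main scaling only. Of 15 ubiquitin and protein quality control genes 7 rose, also 7 adjusted over the list alone (median 0.10, -0.30 when centred with 1 higher and 13 lower; 0.124, not called), with the autophagy receptor Sqstm1 at 0.56 and the neuronal deubiquitinase Uchl1 at 0.47.

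Stress genes divided. Of 16 oxidative stress genes 10 rose and 2 fell, also adjusted over the list alone (median 0.35, -0.05 when centred with 2 higher and 5 lower, camera adjusted p = 0.0066; adjusted p = 0.138 with an estimated correlation), with Mt1 at 2.21. Of 18 lysosome and autophagy genes 12 rose, also 12 adjusted over the list alone (median 0.21, -0.19 when centred with 4 higher and 10 lower, 1.23e-04; adjusted p = 0.138 with an estimated correlation), with Ctsz at 1.11, the progranulin gene Grn at 0.98 and Ctsh at 0.77. Endoplasmic reticulum stress genes were not called (5 higher and 7 lower of 20, and 5 and 8 adjusted over the list alone, 0.481). Their median was -0.03 (-0.43 when centred with 1 higher and 16 lower), the mean above 0 and the test downward. Chac1 rose by 0.93 and Herpud1 by 0.48, while the chaperone Hsp90b1 fell by 0.41 and the sensor Ern1 by 0.33. Heat shock genes were not called (5 higher and 3 lower of 13, also adjusted over the list alone, 0.799), with a median of 0.16 (-0.24 when centred with 0 higher and 8 lower), a mean of -0.04 and the test upward. Hspa1a fell by 1.11, Hspa1b by 1.10 and Hsp90aa1 by 0.41. Of 24 cell death genes 11 rose, and 12 adjusted over the list alone (median 0.15, -0.25 when centred with 2 higher and 17 lower; 0.0597, not called), with the calpain subunits Capn2 at 0.65 and Capns1 at 0.62. Of 17 immediate early genes 7 rose and 1 fell, also adjusted over the list alone (median 0.13, -0.27 when centred with 1 higher and 10 lower; 0.631, not called), with Egr1 at 0.86, Fos at 0.63, Fosb at 0.56 and Ier3 at -1.12. The ages of the window differed, with 7 higher and 1 lower at PN15 (median 0.17, -0.20 when centred) and 0 higher and 4 lower at PN21 (-0.13).

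Metabolic and support genes went both ways. Of 16 glycolysis genes 4 rose and 6 fell, also adjusted over the list alone (median -0.06, -0.46 when centred with 0 higher and 12 lower, camera adjusted p = 0.102, not called), with the hexokinases Hk2 at -1.35 and Hk1 at -0.51, the lactate transporter Slc16a1 at -0.95 and the lactate dehydrogenase Ldha at -0.54. Of 30 oxidative phosphorylation genes 5 rose and 5 fell, also adjusted over the list alone (median 0.01, -0.39 when centred with 0 higher and 30 lower, mean below 0, test downward; 0.578). At PN15 they were 0 higher and 5 lower and at PN21 8 higher and 3 lower (median 0.11, -0.33 when centred). Of 12 outer-segment phospholipid and retinoid genes 4 rose and 6 fell, and 5 and 6 adjusted over the list alone (median -0.15, -0.55 when centred with 0 higher and 8 lower; 0.0504, not called), with the fatty acid elongase Elovl4 at -1.39, Dhrs3 at -1.12 and the acyltransferase Lpcat1 at -0.76. Of 15 vascular genes 2 rose and 7 fell, and 3 and 7 adjusted over the list alone (median -0.07, -0.47 when centred with 1 higher and 13 lower; 0.349, not called). The VEGF receptors Kdr (0.64) and Flt1 (0.48) rose, and the tight junction gene Cldn5 (-0.40) and the pericyte gene Rgs5 (-0.41) fell. Of 13 pigment epithelium genes 10 rose and 1 fell, also adjusted over the list alone (median 0.96, 0.56 when centred with 8 higher and 3 lower, 2.98e-04; adjusted p = 0.138 with an estimated correlation), with Ttr at 1.55, the pigment enzyme Dct at 1.46 and Rgr at 1.21. Pigment epithelium genes averaged 9.00 and 8.99 on the log2 scale in the rd1 arrays of PN21 against 7.47 and 7.49 in WT, and without PN21 the list median was 0.040 (0.832). Lens genes (0 of 16 called by limma, 0 at an unadjusted p under 0.05, median 0.15, -0.25 when centred, mean above 0, test downward, 0.803) were not called. Red blood cell genes (1 lower of 5, 0 adjusted over the list alone, median -0.05, -0.45 when centred with 0 higher and 5 lower, 0.486) and progenitor and cell cycle genes (1 higher and 1 lower of 18, and 1 and 0 adjusted over the list alone, median 0.08, -0.32 when centred with 0 higher and 13 lower, 0.973) were not called either. Camera called 13 lists, and 6 held with an estimated correlation, namely rod and shared photoreceptor genes downward and amacrine, Müller glia, reactive glia and microglia genes upward. Their adjusted p was then 9.96e-04 for rod, 3.24e-04 for shared photoreceptor, 0.0279 for amacrine, 0.0279 for Müller glia, 0.0023 for reactive glia and 1.68e-04 for microglia genes.

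From the early to the middle window the genotype difference itself changed for 399 genes, 210 upward and 189 downward. Without the arrays that held muscle or lens transcripts the count was 228, of which 207 were shared. Fos (2.56 ± 0.12, adjusted p = 1.13e-18), Egr1 (2.08) and Fosb (1.84) moved up most, and Pdzph1 (-0.98), Lrp4 (-0.84) and Fscn2 (-0.71) moved down most. Immediate early genes moved up in 8 of 17 and down in 1 (median 0.23, camera adjusted p = 6.35e-28), and microglia genes up in 10 of 24 (0.28, 4.89e-23). Reactive glia genes moved up in 8 of 23 (0.17, 2.32e-13) and heat shock genes in 3 of 13 (0.10, 3.56e-09). Rod genes moved down in 5 of 17 (median -0.23, 1.16e-14) and shared photoreceptor genes in 4 of 23 (-0.22, 7.11e-17). These 6 lists held with an estimated correlation, at adjusted p of 5.80e-09, 8.63e-06, 4.18e-04, 0.0018, 0.0444 and 0.0235 in the order given. Camera also called endoplasmic reticulum stress (4 of 20 up, 1.41e-06), oxidative stress (2 of 16 up, 6.39e-06) and cell death genes (0 of 24 called by limma, 0.0109) upward. With an estimated correlation their adjusted p was 0.0444, 0.0223 and 0.0444. Under centring the split of calls was 129 upward and 328 downward. From the middle to the late window 5146 genes changed their difference, 3294 upward and 1852 downward (418 and 12752 when centred, with a median shift of all genes of -0.32). B2m (2.39 ± 0.20, 8.28e-13), Serping1 (2.17) and Mt2 (2.10) moved up most and Kcnj14 (-3.69), Pdzph1 (-3.44) and Cnga1 (-3.33) moved down most. All 17 rod genes and all 23 shared photoreceptor genes moved down. Microglia genes moved up in 21 of 24 (median 0.75, 3.45e-15) and Müller glia genes in 13 of 19 (0.56, 2.49e-09), while immediate early genes moved down in 9 of 17 and up in 1 (-0.38, 6.64e-07). Of these 5 lists all held with an estimated correlation (adjusted p of 2.83e-04, 1.96e-04, 2.83e-04, 0.0226 and 0.001).

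Most genes of the middle window kept their direction in the late window. Of 595 genes higher in the middle window 471 were higher in the late window, against 146.8 expected from independent draws (Fisher's exact test, 1-sided, p = 2.03e-178), and 29 were lower. Of 435 lower genes 378 were lower later, against 55.8 expected (6.56e-281), and 9 were higher. Genes are not independent draws, so these p-values describe overlap only.

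In WT retina the rod genes Slc24a1 and Gnat1 were among the largest rises with age, and the proliferation genes Mki67 and Top2a among the largest falls. In all, 6446 genes were higher and 5084 lower in WT at PN15 and PN21 than at PN5 and PN6 (4 against 4 arrays), with 800 rises and 627 falls of at least 2-fold. Centring on amacrine and ganglion cell genes gave 1644 and 13044, with the median of all genes at -0.35 in place of 0.09, and quantile normalization gave 4755 and 5309. The largest rises were Pdzph1 (6.23 ± 0.16), the rod exchanger Slc24a1 (6.02), the rod transducin Gnat1 (5.95), Abca8a (5.75) and the glial water channel Aqp4 (5.66). The largest falls were the radial glial lipid carrier Fabp7 (-4.65 ± 0.11), Mybl1 (-4.62), the proliferation marker Mki67 (-4.56), the topoisomerase Top2a (-4.19) and Vxn (-4.03). Top2a had 3 probe sets, of which 1 was called the opposite way. Pdzph1, which rose most in WT, was among the genes that fell most in rd1 in the late window.

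At PN28 and PN35, with 1 array per genotype and no test, rod genes had median differences of -4.40 and -4.70 and shared photoreceptor genes of -2.68 and -2.74. Amacrine genes were at 0.74 and 0.68 and Müller glia genes at 0.80 and 0.83. Centring on amacrine and ganglion cell genes put the median of all genes at -0.65 at both ages and turned several lists. Microglia genes were at 0.53 and 0.55 (-0.14 and -0.087 when centred), reactive glia genes at 0.32 and 0.62 (-0.35 and -0.017), cone genes at 0.17 and 0.080 (-0.50 and -0.56), and genes of the 20S core at 0.13 and 0.073 (-0.54 and -0.56).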

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

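The splits of the arrays for the tests of change, for WT maturation and for the lists, the muscle test, the PN15 to PN21 and gene-spread tests of glia and the 4 tests on immediate early genes were tests chosen only after the result was seen. The size of the genotype difference depended on age, which was tested directly as the change of the rd1 minus WT difference between windows. From early to middle it changed for 399 genes, with Fos at 2.56, Egr1 at 2.08, Fosb at 1.84, Pdzph1 at -0.98, Lrp4 at -0.84 and Fscn2 at -0.71. From middle to late it changed for 5146 genes, with B2m at 2.39, Serping1 at 2.17, Mt2 at 2.10, Kcnj14 at -3.69, Pdzph1 at -3.44 and Cnga1 at -3.33.

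The arrays were split otherwise within each age, and for WT maturation the 8 arrays of PN5, PN6, PN15 and PN21 were split into 4 and 4 across ages. In the middle window 1 of 100 splits, the real one, gave as many calls (1030, highest other 631), from early to middle 1 of 100 (399, highest other 153) and for WT maturation 1 of 35 (11213 in a simple 2-group fit, highest other 0). Such counts argue against a chance division of the arrays there but do not exclude it. Splits that mix genotypes or ages put real differences into the residual, which lowers their counts. For lists in the middle window 4 of 100 splits gave as many (17), a share under 0.05, but the highest other gave 21, more than the real split, so the number of lists alone does not set the real split apart. In the early window 5 of 100 splits gave as many calls as the real one (15, highest other 231), and 61 of 100 as many lists (5, highest other 13), so chance cannot be excluded, and the split with 231 calls points to a structure of the samples other than genotype. It kept the genotypes apart at PN5 and PN7, set the arrays of PN6 numbered 1 against those numbered 2, and mixed the genotypes at PN8. Among the 6 drawn splits that part all 10 pairs of equal number, as the real one does, the highest other gave 6. From middle to late 6 of 100 splits gave as many (5146, highest other 6252), and all 6 keep every late array in its genotype's group; the largest count among splits that mix late arrays was 4346. For the late window (6823, highest other 4748; lists 13, highest other 18, with 1 and 6 of 18 splits as large) and for single ages with 10 splits the splits are too few for a share under 0.05. The single-age counts and highest others were 3 and 0 at PN7 (1 split as large), 5 and 99 at PN8 (3), 7 and 0 at PN9 (1), 107 and 5 at PN11 (1) and 1364 and 1 at PN13 (1). The 99 calls at PN8 point to a structure among those 6 arrays, and that split set both arrays numbered 1 and WT replicate 2 against both numbered 3 and rd1 replicate 2. Of the 4 splits at PN8 that part all 3 pairs of equal number the highest other than the real one gave 23.

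For the early calls, slower maturation of the rd1 retina of the size set beforehand, a slope under -0.1, is argued against at PN7 and PN8. The slope of their differences on the WT change with age was -0.045 over all genes (-0.087 to -0.019 with single arrays left out). It lay below 0 in each fit, so a smaller delay stays open, and the differences at PN5 and PN6 were not used. Rod and progenitor list medians were 0.17 and -0.22 at PN6 and -0.12 and 0.19 at PN8. Called genes clustered near Pde6b (odds ratio 38.6 within 20 Mb, 1-sided Fisher's exact test p = 1.64e-07), which is consistent with strain DNA carried along with the mutation, although 46.2% of the 13 other calls with a position (6, exact 95% interval 19.2% to 74.9%) leaves open whether that accounts for most of them. Without the muscle and lens arrays 7 calls were left, of which 6, Pde6b included, lay within 20 Mb and 1 had no known position. Muscle left on rd1 samples of PN5 and PN6 may account for the muscle genes, since 20 other muscle genes that were not called had a median of 0.20 at PN5 and 18 of them were higher. At PN6 the mean of the muscle genes was 6.13 in rd1 replicate 1 but 5.88 in rd1 replicate 2, against 5.89 and 5.92 in WT. Replicate 2 was thus not above WT. Of 25 muscle genes 1 lay above the median gene in WT retina and 0 are in another list, Acta1 and Tnnc2 were the largest called members (1.85 and 1.75 at PN5), and an effect of the mutation itself on these genes stays open.

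The late rises of microglia and reactive glia genes were weighed against a lower share of rod RNA, which would raise all other cell types alike. The rise of Müller glia genes was not tested in this way, and rod share stays open for it. The microglia median exceeded the inner neuron median of 0.46 by 0.60 (SE 0.13), which passes the 0.5 that rod share allows by less than the SE and does not exclude it. From PN15 to PN21 the gap of the microglia mean over inner neurons changed by -0.72 (SE 0.10, from 0.97 to 0.25) while the rod mean fell by 2.23, which argues against rod share as the whole cause. For reactive glia the excess of the median was 0.24 (SE 0.25), within that 0.5, so rod share stays open for the list as a whole. However, 7 of 23 genes lay over 0.5 above the inner neuron median by more than 2 SE. Of 53 inner neuron genes, each against the median of the other inner neuron lists, 0 did so (2-sided Fisher's exact test p = 1.12e-04). Genes share the same arrays and are not independent draws, so this p-value describes the 2 sets of genes only. The values of the 7 genes argue against rod share as the whole cause for part of the list. A lower rod share may still add to both rises, and more cells or more transcript per cell stay open.

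For the middle rise of immediate early genes, handling that differed between genotypes at every age, with a like response at each age, is argued against. The list mean over PN5 to PN8 lay at -0.79 (SE 0.03) relative to PN11 to PN13. A response to handling that grew with age was not tested and stays open. Microglia bringing these transcripts at a steady amount per cell is argued against. The list mean changed by -0.72 (SE 0.05) from PN11 and PN12 to PN15 and PN21 while the microglia mean changed by 0.80 (SE 0.05). Which cells held the transcripts was not measured, so a passing rise within microglia stays open. Handling that differed only from PN11 to PN15 is argued against by the list mean at PN9, which was 0.20 (SE 0.04). Handling that differed on the days of PN9 to PN15 cannot be told apart from a change in the tissue, since every rd1 array lay above every WT array at 5 of 5 of these ages, as both would give, and no collection dates are given. A response of the rd1 retina around the onset of rod loss may account for the rise and stays open.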

How the results depend on the processing

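The left-out ages and the left-out muscle and lens arrays were tests chosen only after the result was seen. The cause of each change below was not tested unless the setting removes arrays or genes or shifts all genes by construction. Centring on amacrine and ganglion cell genes, which shifts all genes, gave 11647 calls at PN15, 13551 at PN21, 15202 in the late window and 13170 from middle to late; Psmd14 at -0.11 (0.174) and Psma4 at -0.19 (0.0032), Lrrc8c at -0.13 (0.0558) and Tmod2 at -0.044 (0.773) in the late window; microglia genes at -0.14 and -0.087, rod genes at -5.07 and -5.33 and Müller glia genes at 0.13 and 0.19 at PN28 and PN35. The mean of all probe sets gave rod genes of -3.47 and -3.80 at PN28 and PN35 and Rpap2 at -0.19 (0.0481) in the early window. Leaving out dim genes gave 4 calls at PN5. Array weights gave 20 calls at PN5, 3 at PN8, 11 at PN9, 224 at PN11 and 2 lists in the early window. A fit of the compared arrays alone, with fewer residual degrees of freedom, gave 4 calls at PN5, 3 at PN8 and 61 at PN11, and Pde6b at -1.49 (adjusted p = 0.509) at PN5 and -0.81 (7.99e-04) at PN6. An estimated correlation gave 0, 9 and 6 lists in the early, middle and late windows, and fry 0 lists early and 21 late.

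Without PN5 the early window had 8 calls (7 shared) and without the muscle and lens arrays 7, all shared, while the lens median became 0.17 (0.0686). Without those arrays 228 genes changed from early to middle (207 shared). Without PN13 the middle window had 229 calls and 11 lists, with pigment epithelium genes at 0.014 (0.987). Without PN21 the late window had 3947 calls, with pigment epithelium genes at 0.040 (0.832). Leaving out 1 array at a time, where a lone remaining array is assumed to vary like the other groups, gave 6 to 23 calls at PN5, 1 to 6 at PN6, 3 to 9 at PN7, 3 to 49 at PN8, 57 to 93 at PN11, 62 to 133 at PN12, 2294 to 3611 at PN15, 9 to 22 in the early window and 2 to 9 lists there, with the lens median at 0.12 (0.368) without WT PN7 replicate 3. Of 196 values of named genes, 194 kept direction and call under quantile normalization, 195 without a trend, 194 with array weights, 190 with the mean of all probe sets and 183 when centred. Of 35 list calls by camera, 33 kept the direction and call of the test under quantile normalization, 15 with an estimated correlation and 26 with fry. Camera sets a list against the other genes, so centring hardly moves it by construction and says nothing on its stability, while the list medians of the late ganglion cell, oxidative stress and lysosome calls turned. Counts in the middle (801 to 1052) and late window (5854 to 6683) stayed within 1.5 times.

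The replicate number as a block gave 14, 1026 and 6853 calls in the 3 windows, and for WT maturation it could not be estimated. It ended the calls of Tnnt3 (0.340), Tlcd3a (0.101) and Myh8 (0.0873) in the early window. Over the series the numbers do not pair the samples, since 1 of 5 ages with 3 pairs had every correlation between the deviations of equal numbers above 0.1, and 5 of 15 arrays matched their own number best. That age was PN8 (0.148 to 0.339), where the block gave 4 calls in place of 5. At the ages with 2 pairs the correlations were 0.180 at PN5, 0.198 at PN6, -0.103 at PN12, 0.104 at PN15 and 0.034 at PN21. No dilution or background values were used here, so what weak signal limits was read only from leaving out dim genes.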

Other observations

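Genes that turned around between the middle and late windows were read after their values were seen. The inducible chaperones Hspa1b and Hspa1a moved from 1.54 and 1.26 in the middle window to -1.10 and -1.11 in the late window, a change of -2.64 and -2.37 between the windows. At PN15 they were at 0.26 and -0.05 and at PN21 at -2.46 and -2.17. Aqp1, a water channel, moved from 0.48 to -1.94. Genes of the pigment epithelium moved the other way, with Rgr from -0.45 to 1.21, Rpe65 from -0.43 to 1.11 and Pon1, a lactonase, from -0.26 to 1.27. Rgr was at 0.04 at PN15 and 2.38 at PN21, and Rpe65 at -0.03 and 2.26. In the single arrays of PN28 and PN35 Rgr was at -0.27 and -0.09 and Rpe65 at -0.38 and -0.45. How much pigment epithelium stayed on each retina was not measured, so these values do not show a change within the neural retina.

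Interferon and antigen presentation genes differed widely between single arrays of the oldest ages, with a median of -0.83 at PN28 and 0.64 at PN35, and Usp18 at -2.92 and 0.67. When centred on amacrine and ganglion cell genes the list medians were -1.50 and 0.0034. Immunoproteasome genes were at 0.064 and 0.64 (-0.60 and 0.0046 when centred on amacrine and ganglion cell genes) and lens genes at 1.18 and 1.90. Bipolar genes were at 0.56 at both ages (-0.11 and -0.072 when centred), ganglion cell genes at 0.77 and 0.73, Hspa1b at -2.44 at both, and Fos at -0.32 and 0.13.

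Lens genes averaged 12.56 on the log2 scale in WT PN7 replicate 3, 10.18 in rd1 PN21 replicate 1 and 9.55 in the rd1 array of PN35. Most arrays showed both the X-inactivation transcript Xist and the Y-linked Eif2s3y, as a pool of animals of both sexes would. Xist was low in WT PN7 replicate 2 (7.74) and WT PN8 replicate 2 (7.53), and Eif2s3y was low in rd1 PN7 replicate 2 (3.95), rd1 PN9 replicate 1 (3.56) and rd1 PN11 replicate 3 (3.75).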
